A study of Mus musculus with 9 samples.

How the data were processed

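Poly(A) RNA was sequenced from the colon of 9 C57BL/6 mice in 3 groups of 3 mice. The NC group was the control, the MC group received dextran sulfate sodium (DSS), a polymer that injures the colon epithelium, and the LRWE group received DSS with an extract of Linderae Radix, the root of Lindera aggregata, at 2.0 g/kg. Modelling with DSS lasted 9 days. Each library came from a different mouse, so every replicate is a biological one. The segment of colon taken from each mouse is not given in the sources used here.

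The deposited table held 36256 genes with mouse Ensembl identifiers, symbols, coordinates and annotation terms, and 18 columns of values, all of which were used. Per the file headers, 9 columns held FPKM, fragments scaled by the authors to transcript length and library size. Per the file headers, the other 9 columns held counts, whole numbers taken here to be expected counts, which the notes do not state. In genes with 1 transcript in GENCODE M21, counts divided by FPKM and length were the same to 3 digits between the quartiles of genes with over 500 counts. In genes with under 6 counts the median of this ratio was 1.18 to 1.25 times as high, as it would be for coverage estimates rounded up. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR without a version, with no settings. The notes name the build hg38, which cannot be the build of mouse identifiers, and the position of Gnai3 differed from that in the mouse GRCm38 annotation, so coordinates are given as in the deposited table with the build not named.

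Library totals ran from 59042063 to 65042857 counts, and 34101 genes had a count in at least 1 library. The median standard error of a log2 fold change was 0.415 for MC against NC, 0.413 for LRWE against MC and 0.414 for LRWE against NC. The median 95% half-width was 0.937, 0.933 and 0.937 in the same order. For the fold of a gene, a group at 0 counts was set at a floor of 3 counts over its 3 libraries. List means use fitted values, and the mean with the floor is added for described lists where members at 0 moved it noticeably. Standard errors and intervals cover spread between mice together with counting error, while the floors behind each "at least" cover counting error alone. Reads without molecular identifiers are not independent molecules.

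Before the data were examined, the comparisons, the gene lists, the rule for naming genes, the planned test and a set of alternatives were fixed. Further alternatives were added afterwards. The planned test was limma-trend on log2(FPKM + 1), because the table was named as one of FPKM. The table also held counts, so edgeR's quasi-likelihood test on counts became the main test and the planned one became an alternative. Genes were kept by filterByExpr (21767 of 36256), libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 9 libraries in edgeR 4.0.16 under R 4.3.3. Adjusted p-values of genes are from edgeR with the Benjamini-Hochberg method over 21767 genes, and a gene was called at an adjusted p under 0.05. CPM are counts scaled to library size after TMM, and log2 CPM used a prior count of 2. SE is an approximate standard error of a log2 fold change, with n = 3 mice per group. It is the absolute log2 fold change divided by the square root of edgeR's F statistic, and is uncertain where counts are low.

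The question of the study, from its title, is whether the extract lowers JAK/STAT signalling in colitis. Lists of 11 JAK/STAT kinases and transcription factors (the core list) and of 22 targets and feedback genes were fixed for it, in a set of 24 pathway lists, 21 cell type lists and 3 quality lists. Only RNA was measured, so the core list does not measure the activity of these kinases and factors, which the question concerns. Of 1037 listed symbols, 1018 matched a symbol in the table, 1 matched through the GENCODE M21 names and 18 had no match. Lists were tested on edgeR log counts with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 48 lists. Each list was tested again with an estimated correlation, and with fry, which asks whether the members of a list move one way on balance. The annotation terms of the table (1584 GO and 315 KEGG terms with 15 to 500 tested genes) were tested with camera in the same way. A list score is the mean log2 CPM of the members in a library minus the NC mean.

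Genes named in the report came from 3 sources. The first was the 8 largest rises and 8 largest falls among called genes whose groups did not overlap (5 and 5 for LRWE against NC, and the 5 smallest p in each direction where no gene passed), leaving out predicted loci, pseudogenes and immunoglobulin segments. The second was up to 4 called members of each list described, or its 2 most abundant members where fewer than 2 passed. The last was members of the core list with Socs3, Il6, Il1b, Tnf, Muc2, Tjp1, Ocln and Cldn1. A gene named for one comparison may be named in the others, and a gene outside the rule is said to be chosen after its values were seen.

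Alternatives covered filters on low values, pseudocounts of 1, 0.1 and 0.5 on FPKM, scalings of counts and FPKM, library quality weights, DESeq2 1.42.0, other thresholds and leaving out each library in turn, 33 fits of each comparison. Both comparisons with NC share the same control libraries, and both comparisons with MC share the MC libraries. To gauge this, 100 simulations of unchanged groups gave the values that sharing produces where genes vary independently, with no deviation common to a library. The test was tested on simulated data with 200 changed genes. For MC against NC it recovered 4.21% of genes changed by 1 and 32.6% of genes changed by 2 on the log2 scale, over 20718 genes, and 4 of its 38 calls were unchanged genes. For LRWE against MC it recovered 3.33% and 30.9% over 20726 genes, and 1 of its 33 calls was an unchanged gene. Recovery with more changed genes was not simulated. Permuting 3 against 3 libraries cannot give a p below 0.1, so no permutation p is given for the comparisons, and splits of the libraries are only counted. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.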

Results

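RNA abundance was measured in the colon of 9 C57BL/6 mice. Of these, 3 were control mice (NC 1 to NC 3), 3 were mice with DSS colitis (MC 1 to MC 3) and 3 were mice given DSS and Linderae Radix extract at 2.0 g/kg (LRWE 1 to LRWE 3). Library totals were 61604692, 64202896 and 63127130 counts in NC, 61216850, 59771026 and 60537329 in MC, and 59042063, 64198910 and 65042857 in LRWE. The mitochondrial chromosome took 16.17% ± 3.53 of counts in NC, 14.49% ± 4.04 in MC and 12.33% ± 1.61 in LRWE (mean ± SD, n = 3). Between 21218 genes (LRWE 2) and 26019 genes (NC 3) had a count. Fold changes are log2 fold changes ± SE, and both they and the edgeR p-values measure the spread between mice, 3 per group.

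Libraries of 1 group correlated at r = 0.9527 to 0.9608 in NC, 0.9244 to 0.9494 in MC and 0.8943 to 0.9394 in LRWE, across genes, which are not independent replicates. The median SD of log2 CPM was 0.253 in NC, 0.379 in MC and 0.474 in LRWE. LRWE 2 stood apart on the first principal component, at 220.1, with LRWE 3 at 74.6 and LRWE 1 at 5.571. LRWE 2 had the lowest quality weight of the 9 libraries (0.247), followed by MC 2 (0.385) and LRWE 1 (0.494).

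**Figure D1:**
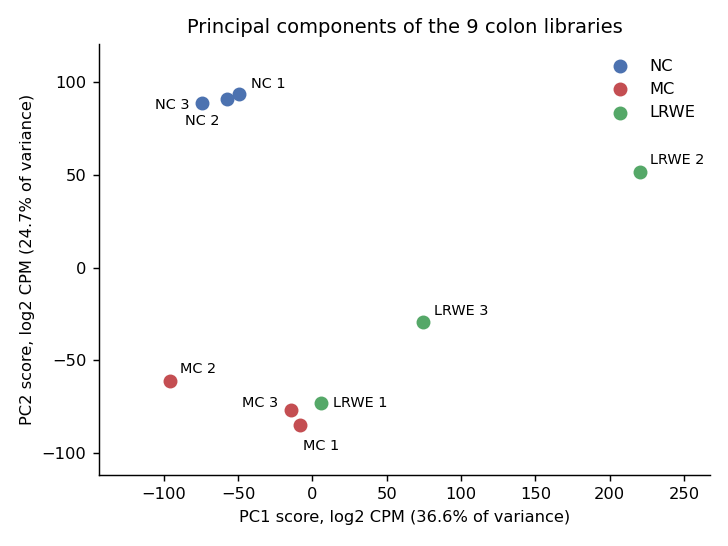
Principal components of log2 CPM over all tested genes, with 1 point per library coloured by group, component 1 (36.6% of variance) on the horizontal axis and component 2 (24.7%) on the vertical axis. The 3 NC libraries sit together at -49.67 to -74.29 on component 1, and LRWE 2 lies at 220.1.

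The comparison of MC with NC asks what DSS changed in the colon, and transcripts of antimicrobial proteins rose. Reg3b (ENSMUSG00000071356, chromosome 6, 78347640 to 78350449, plus strand, build not named), a lectin that binds bacteria, went from 1.69 CPM in NC to 499.6 CPM in MC (log2 fold change 8.21 ± 0.83, adjusted p = 0.00355). Its neighbour Reg3g rose by 7.67 ± 0.90 (adjusted p = 0.00450). Reg3a was at 0 in NC and at least 35.5-fold higher in MC (adjusted p = 0.0126). Reg3 genes are related paralogues, and reads shared between them were not tested. Saa3, an acute-phase protein, rose from 0.552 to 34.7 CPM (5.97 ± 0.37, adjusted p = 0.00119, the smallest of the 21767 genes). Of the 23 members of the antimicrobial list, 6 were called and all rose (10 higher and 2 lower adjusted over the list alone), with a list mean of 2.25. Camera gave this list an adjusted p of 2.72e-05 (adjusted p = 0.492 with an estimated correlation). Scores of epithelial antimicrobial defence were 0.71 in MC 1, 2.05 in MC 2 and 2.00 in MC 3, and those of neutrophils were 0.36, 3.00 and 2.57, so the cells behind the rise are not settled. The list of neutrophils had no called member, a mean of 2.52 (2.36 with groups at 0 set at the floor) and a camera adjusted p of 0.0174 (adjusted p = 0.854 with an estimated correlation), and its call was lost without MC 2 (0.169), MC 3 (0.0553) or LRWE 2 (0.0515). The mean of neutrophils ran from -0.05 to 4.34 over 32 alternatives, and the camera direction was up in 31 of them. Ceacam12, at 0 in NC, was at least 84.9-fold higher (adjusted p = 0.00796). The calls of Reg3a, Reg3b, Reg3g, Saa3 and Ceacam12 held in each fit that left out 1 library.

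Epithelial transporters fell. Slc20a1, a sodium-phosphate transporter, went from 1329 to 127.3 CPM (-3.38 ± 0.40, adjusted p = 0.00451). Slc26a3, the chloride-bicarbonate exchanger of colonocytes, went from 2178 to 248.3 CPM (-3.13 ± 0.43, adjusted p = 0.00723). The bicarbonate channel Best2 changed by -2.47 ± 0.27 (adjusted p = 0.00428). The ion and water transport list had 9 of 26 members lower and 3 higher (13 and 4 adjusted over the list alone), with a mean of -0.69 and a median of -1.02. Camera gave it an adjusted p of 8.84e-08 (adjusted p = 0.492 with an estimated correlation). The 3 members that rose were the bile acid transporter subunits Slc51a (6.47 ± 1.57, adjusted p = 0.0446) and Slc51b (1.38 ± 0.26, adjusted p = 0.0191) and the sodium-proton exchanger Slc9a3 (2.09 ± 0.40, adjusted p = 0.0195). Slc51b and Slc9a3 were chosen after their values were seen. Slc51a stood at 0.445 CPM in MC 2, against 173.6 in MC 1, 55.75 in MC 3 and 0.667 to 1.20 in NC. The calls of Slc51a, Slc51b and Slc9a3 were lost without NC 1, NC 2, MC 1 or MC 3, those of Slc51a and Slc51b without NC 3, and that of Slc51a without LRWE 3 (adjusted p 0.0544 to 0.173).

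Among junction proteins, occludin (Ocln) fell from 132.1 to 41.2 CPM (-1.68 ± 0.26, adjusted p = 0.0102). Marveld3, of the same tetraspan family, fell from 90.1 to 26.5 CPM (-1.76 ± 0.24, adjusted p = 0.00723). Both calls held without each library. Tjp1 (-0.53 ± 0.17, adjusted p = 0.0969) and Cldn1 (-2.40 ± 1.17, adjusted p = 0.249) did not pass. The list of tight and adherens junctions had these 2 of 22 members lower (4 adjusted over the list alone), with a mean of -0.49 and a camera adjusted p of 0.0126 (adjusted p = 0.82 with an estimated correlation). The list call was lost without NC 2 (adjusted p = 0.0537) or MC 2 (adjusted p = 0.11).

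Goblet cell transcripts went both ways. Muc2, the main secreted mucin of the colon, rose from 493.8 to 1220 CPM (1.31 ± 0.29, adjusted p = 0.0339), and Retnlb, a secreted goblet cell protein, rose by 5.14 ± 1.15 (adjusted p = 0.0340). Creb3l1 fell by 1.39 on the log2 scale (SE 0.19, adjusted p = 0.00713), and so did Agr2, needed for mucin folding (-1.07 ± 0.20, adjusted p = 0.0189). These 4 were the called members among 20 (2 higher and 6 lower adjusted over the list alone). The mean of the list of goblet cells was -0.04 (camera adjusted p = 0.231), with a median of -0.19, and the mean turned positive with library totals as scaling (0.11). The call of Creb3l1 held without each library. Those of Muc2, Retnlb and Agr2 were lost without NC 1, NC 2 or NC 3, those of Muc2 and Retnlb without MC 3, those of Muc2 and Agr2 without MC 1, that of Retnlb without MC 2 and that of Muc2 without LRWE 3 (adjusted p 0.0540 to 0.148).

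Genes of stem and crypt base cells fell while wound-associated epithelial genes rose. Sox9, a transcription factor of the crypt, fell from 23.3 to 5.90 CPM (-1.98 ± 0.30, adjusted p = 0.00900), a call that held without each library. Reg4 (-4.70 ± 0.84, adjusted p = 0.0164) and the stem cell factor Ascl2 (-5.36 ± 1.31, adjusted p = 0.0457) fell and Prom1 rose (1.5 ± 0.29, adjusted p = 0.0202). The crypt list had these 4 called members of 16 (1 higher and 7 lower adjusted over the list alone), a mean of -1.13 and a camera adjusted p of 0.0233 (adjusted p = 0.52 with an estimated correlation), and without MC 3 the camera value was 0.0514. Emp1 (3.22 ± 0.49, adjusted p = 0.00929), the urokinase receptor Plaur (2.98 ± 0.64, adjusted p = 0.0291) and the collagen receptor subunit Itga2 (2.31 ± 0.42, adjusted p = 0.0171) were the 3 called members of 24 in the wound list (5 adjusted over the list alone). The list of wound-associated epithelium had a mean of 0.90 (0.47 without MC 2) and a camera adjusted p of 0.00883 (adjusted p = 0.492 with an estimated correlation). Without NC 2 the calls of Reg4, Ascl2, Prom1, Emp1, Plaur and Itga2 were lost, as were all of these but Emp1 without NC 1 or MC 3, those of Ascl2, Prom1, Plaur and Itga2 without NC 3, of Ascl2, Prom1 and Itga2 without MC 1, and of Ascl2 and Plaur without MC 2 (adjusted p 0.0515 to 0.146).

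Antibody transcripts fell and the glial gene Gfap rose. Jchain, which joins IgA units in plasma cells, fell from 339.6 to 22.98 CPM (-3.88 ± 0.60, adjusted p = 0.00995). Igha (-3.52 ± 0.64, adjusted p = 0.0176) and Igkc (-3.88 ± 0.78, adjusted p = 0.0236, chosen after its values were seen) also fell, but immunoglobulin genes share reads and their values are uncertain. These were the 3 called members of 25 in the B and plasma cell list (1 higher and 5 lower adjusted over the list alone), which had a mean of -2.32 and a camera adjusted p of 2.72e-05 (adjusted p = 0.697 with an estimated correlation). The list score differed between mice of 1 group, from -1.06 to 1.76 in NC and from -4.53 to -0.51 in MC, and the mean of B and plasma cells was -0.79 without NC 3 and -4.91 without MC 2. Gfap, a filament protein of enteric glia, rose from 5.76 to 112.8 CPM (4.29 ± 0.51, adjusted p = 0.00461). Gfap was the 1 called member of 20 in the neuron and glia list (16 higher and 1 lower adjusted over the list alone), with a list mean of 1.72 and a camera adjusted p of 5.45e-08 (adjusted p = 0.618 with an estimated correlation). Cela1, a protease of the pancreatic list, fell (-2.71 ± 0.35, adjusted p = 0.00548), and so did the muscle enolase Eno3 (-2.40 ± 0.35, adjusted p = 0.00857). The calls of Jchain, Gfap, Cela1 and Eno3 held without each library. The call of Igkc was lost without NC 1, NC 2, NC 3, MC 1 or MC 3, and that of Igha without NC 2, NC 3 or MC 3 (adjusted p 0.0546 to 0.0914).

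Genes that mark position along the colon also differed. Hoxb genes of the proximal list rose, with Hoxb5 from 17.8 to 78.3 CPM (2.14 ± 0.20, adjusted p = 0.00224, chosen after its values were seen), Hoxb6 (3.49 ± 0.66, adjusted p = 0.0195) and Hoxb8 (4.13 ± 0.97, adjusted p = 0.0401). Osr2 rose too (5.67 ± 1.3, adjusted p = 0.0373). Slc37a2, listed as distal, fell from 882.2 to 14.82 CPM (-5.89 ± 0.77, adjusted p = 0.00568), and Sfrp2 fell (-1.69 ± 0.36, adjusted p = 0.0307). The distal factors Hoxb13 and Hoxd13 both had -3.64 ± 1.37 (adjusted p = 0.145), with MC 2 at 61.2 CPM of Hoxb13 against 1.18 in MC 1 and 9.70 in MC 3, and without MC 2 the call of Hoxd13 passed (adjusted p = 0.00515). The proximal list had 7 of 12 members higher and 1 lower (7 and 3 adjusted over the list alone), a mean of 1.43 and a camera adjusted p of 0.000711 (adjusted p = 0.618 with an estimated correlation). The 1 lower member was Gsdmc3 (-1.91 ± 0.46, adjusted p = 0.0440), chosen after its values were seen. The distal list had Slc37a2 and Sfrp2 as its 2 called members of 11 (2 higher and 4 lower adjusted over the list alone), a mean of -0.86 (-1.13 with groups at 0 set at the floor), a median of -1.64 and a camera adjusted p of 0.0233 (adjusted p = 0.492 with an estimated correlation). The calls of Hoxb5 and Slc37a2 held without each library. Those of Hoxb6, Hoxb8, Osr2, Sfrp2 and Gsdmc3 were lost without NC 1, NC 2, NC 3 or MC 3, those of all but Gsdmc3 without MC 1, those of Sfrp2 and Gsdmc3 without MC 2, and those of Hoxb8, Osr2 and Gsdmc3 without LRWE 3 (adjusted p 0.0513 to 0.157).

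**Figure D2:**
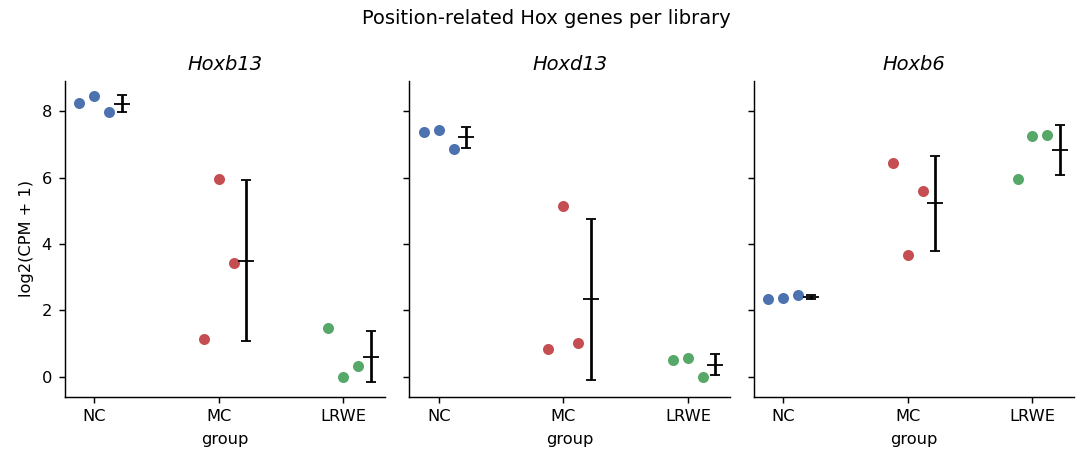
Abundance of Hoxb13, Hoxd13 and Hoxb6 as log2(CPM + 1) in each library, with 1 point per mouse and a bar for the mean ± SD of each group (n = 3). Hoxb13 lay at 248 to 352 CPM in NC, 1.18 to 61.2 in MC and 0 to 1.79 in LRWE, and Hoxb6 at 4.11 to 4.55 CPM in NC, 11.6 to 85.5 in MC and 61.2 to 156 in LRWE.

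Ribosomal protein transcripts fell together. Rpl32 went from 517.4 to 168.9 CPM (-1.62 ± 0.24, adjusted p = 0.00901) and Rps19 from 228.8 to 80.1 CPM (-1.51 ± 0.22, adjusted p = 0.00832), and both calls held without each library. Of the 40 listed genes, 30 were lower (39 adjusted over the list alone), with a mean of -1.04 that was negative under each scaling tried. Camera gave an adjusted p of 2.33e-31 (adjusted p = 0.492 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so the value of any one of them is uncertain.

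The study's title names JAK/STAT signalling, so the choice of these genes is not independent evidence. Their RNA abundance does not measure the activity of the proteins. Stat3 (ENSMUSG00000004040, chromosome 11, 100775924 to 100830366, minus strand, build not named), the factor downstream of IL-6 and IL-22, rose from 74.9 to 177.7 CPM (1.25 ± 0.31, adjusted p = 0.0488). The other core genes given here did not pass in edgeR. Values were 0.14 ± 0.18 for Jak1, -0.31 ± 0.15 for Jak2, 0.37 ± 0.33 for Jak3 and -0.54 ± 0.17 for Tyk2 (adjusted p 0.098 to 0.697). They were 0.66 ± 0.26 for Stat2, -0.52 ± 0.69 for Stat4, 0.26 ± 0.38 for Stat5a, 0.59 ± 0.16 for Stat5b and 0.23 ± 0.12 for Stat6 (adjusted p 0.0623 to 0.732). Adjusted over the list alone, 2 of the 11 were higher and 1 lower, with a list mean of 0.23 (camera adjusted p = 0.252). Stat5b passed without LRWE 1 or LRWE 2 (adjusted p 0.0335 to 0.0487), and the call of Stat3 was lost without any 1 of NC 1, NC 2, NC 3, MC 1, MC 2, MC 3 and LRWE 3 (adjusted p 0.0598 to 0.161), with a value of 0.79 without MC 2.

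Among targets and feedback genes of the pathway, Bcl2l1, an anti-apoptotic protein, rose from 25.7 to 59.7 CPM (1.22 ± 0.13, adjusted p = 0.00428), a call that held without each library. Bcl3 (1.66 ± 0.41, adjusted p = 0.0459), Il4ra (1.4 ± 0.25, adjusted p = 0.0161) and Pim1 (1.31 ± 0.25, adjusted p = 0.0213) rose. Mcl1, chosen after its values were seen, fell (-1.12 ± 0.20, adjusted p = 0.0176). The feedback inhibitor Socs3 went from 13.6 to 81.7 CPM without passing (2.58 ± 0.72, adjusted p = 0.0678, and 0.0496 without LRWE 2), and without MC 2 it was 1.27 (adjusted p = 0.144). With Stat3, the list of JAK/STAT targets and feedback had 5 of 22 members higher and 1 lower (6 and 1 adjusted over the list alone), a mean of 0.55 and a camera adjusted p of 0.0173 (adjusted p = 0.618 with an estimated correlation). The list score was 0.94 in MC 2, against 0.18 in MC 1 and 0.20 in MC 3, and the list call was lost without MC 2 (mean 0.20, adjusted p = 0.153) or LRWE 2 (adjusted p = 0.0525). The calls of Bcl3, Il4ra, Pim1 and Mcl1 were lost without NC 1 or NC 2, those of Bcl3 and Pim1 without NC 3, those of Il4ra and Mcl1 without MC 1, those of Bcl3 and Mcl1 without MC 3, and that of Bcl3 without MC 2 or LRWE 3 (adjusted p 0.0516 to 0.162).

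Other large differences were in genes listed at 0 in 1 of the groups. Klk15, a serine protease, was at least 105-fold lower in MC (adjusted p = 0.0269), Serpina9 at least 103-fold lower (adjusted p = 0.0243), the dendritic cell lectin Cd207 at least 96.5-fold lower (adjusted p = 0.0291) and Atp13a4 at least 86.6-fold lower (adjusted p = 0.0272). The serotonin receptor Htr2c was at least 59.4-fold higher (adjusted p = 0.0179) and Btn1a1 at least 55.1-fold higher (adjusted p = 0.0195). These 6 calls were lost without NC 1, NC 2, NC 3 or MC 3, and those of all but Btn1a1 without MC 1 (adjusted p 0.0515 to 0.137).

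Inflammatory cytokines varied between the MC mice. Il6 was at 0 in NC and at least 43.0-fold higher in MC (adjusted p = 0.173), which MC 2 carried, with 2.02 CPM against 0 in MC 1 and 0.0664 in MC 3. Il1b had 3.18 ± 1.48 (adjusted p = 0.228) and Tnf 2.23 ± 0.70 (adjusted p = 0.0926, and 0.0329 without LRWE 3). The list of inflammatory cytokines had a mean of 1.53 and a median of -0.00494 (camera adjusted p = 0.495), with a mean of 1.06 when groups at 0 are set at the floor, and its score was -0.47 in MC 1, 1.84 in MC 2 and 0.48 in MC 3. Without MC 2 its mean was -0.31.

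In the whole table, 618 genes were higher and 768 lower in MC than in NC, 1386 or 6.37% of the 21767 tested, and 933 of them by at least 2-fold. The groups did not overlap for 8626 genes, 39.6% of those tested, where chance gives 10% on average over splits of the libraries. Genes of a library vary together, so the share of a single split can lie far from 10% without any effect. The count of calls was 281 without NC 1, 308 without NC 2, 476 without NC 3, 520 without MC 1, 506 without MC 3 and 3318 without LRWE 2. With library totals as scaling the calls were 783 higher and 539 lower, with FPKM set to the same sum 908 and 536, and with FPKM scaled to genes under 1% of the sum 1651 and 920. Scaling by library totals shifted the median log2 fold change of all genes to 0.143. Of the 48 lists, 10 rose and 9 fell, and none held with an estimated correlation. Among 75 called genes that were followed through every alternative, all kept their sign and 25 were called in each fit that left out 1 library.

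**Figure D3:**
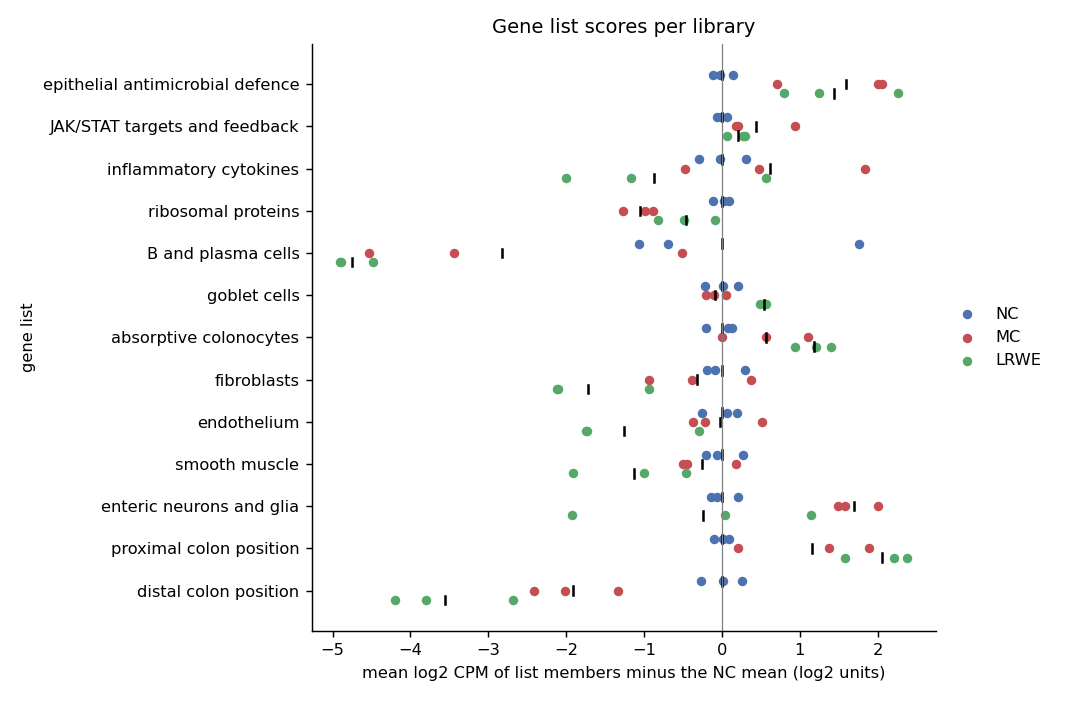
List scores of 13 gene lists, the mean log2 CPM of the members minus the NC mean (horizontal axis), with 1 point per library, coloured by group, and a black tick at each group mean (n = 3). The distal position list lies at -2.41 to -1.33 in MC and -4.20 to -2.68 in LRWE, and the neuron and glia list at 1.49 to 2.00 in MC and -1.93 to 1.14 in LRWE.

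The comparison of LRWE with MC asks what the extract changed in mice given DSS, and no single gene passed. The smallest adjusted p was 0.164. Genes at that value included Sdc1, an epithelial and plasma cell proteoglycan, at 79.3 CPM in MC and 164.7 in LRWE (1.05 ± 0.18), the zinc exporter Slc30a1 (1.02 ± 0.18), Yipf1 (0.98 ± 0.16), Pex7 (0.90 ± 0.16) and Selenos (0.87 ± 0.16). In the other direction, also at 0.164, were the somatostatin receptor Sstr2 (-2.83 ± 0.49), Pard6g (-1.54 ± 0.29), Tead2 (-1.43 ± 0.25) and Mthfsd (-0.93 ± 0.15). Actc1, a cardiac and smooth muscle actin, was at 0 in LRWE, at least 173-fold lower. In edgeR 0 of 21767 genes passed, with 5139 at an unadjusted p under 0.05. Limma-trend on FPKM also gave 0 calls, DESeq2 gave 2001, voom with quality weights 2901 and limma with arrayWeights 4842. Groups did not overlap for 6188 genes (28.4%, where chance gives 10% on average over splits). Because genes vary together within libraries, this share does not show that many genes responded to the extract. Without LRWE 1, 950 genes were higher and 1486 lower in edgeR, and without MC 3 1 gene passed. The 10 genes named here passed without LRWE 1 (adjusted p 0.031 to 0.04).

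Some epithelial lists were higher in LRWE than in MC. Others did not pass, with a mean of 0.05 for stem and crypt base cells, -0.03 for enteroendocrine and tuft cells and -0.36 for wound-associated epithelium (camera adjusted p = 0.865 for each) and of -0.36 for the antimicrobial list (camera adjusted p = 0.477). The camera direction was up for the wound and antimicrobial lists despite their negative means, and 13 of 23 antimicrobial members were positive, with a median of 0.215. All 20 members of the list of goblet cells had positive values, with a mean of 0.57 and a camera adjusted p of 1.38e-05 (adjusted p = 0.171 with an estimated correlation, and 0.0131 by fry). Muc2 had 0.92 ± 0.29 (adjusted p = 0.164), at 2303 CPM in LRWE. The ion and water transport list rose by 0.37, with 7 members higher and 1 lower adjusted over the list alone (camera adjusted p = 9.47e-06, adjusted p = 0.526 with an estimated correlation), Best2 among them at 0.84 ± 0.26 (adjusted p = 0.164, and 0.0454 without LRWE 1). Slc26a3 had 0.14 (adjusted p = 0.863) and Slc20a1 0.18 (adjusted p = 0.8). The junction list had a mean of 0.35 (camera adjusted p = 0.000189, adjusted p = 0.545 with an estimated correlation), with Ocln at 0.76 ± 0.26 (adjusted p = 0.167), Tjp1 at -0.01 ± 0.17 (adjusted p = 0.99) and Cldn1 at -0.86 ± 1.15 (adjusted p = 0.676).

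Metabolic lists were higher as well. Oxidative phosphorylation had a mean of 0.67, with 23 of 29 members higher adjusted over the list alone (camera adjusted p = 8.46e-13, adjusted p = 0.544 with an estimated correlation). The ATP synthase subunits Atp5a1 (0.74 ± 0.21) and Atp5b (0.57 ± 0.17) both had an adjusted p of 0.164, and Atp5a1 passed without LRWE 1 (adjusted p = 0.0404). Ribosomal proteins had a mean of 0.60, with 24 of 40 higher adjusted over the list alone (camera adjusted p = 6.92e-14, adjusted p = 0.544 with an estimated correlation). The list of PPAR targets and fatty acid oxidation had a mean of 0.86 (0.59 without MC 2), with 11 of 26 higher adjusted over the list alone (camera adjusted p = 3.68e-10, adjusted p = 0.544 with an estimated correlation). Its score was -0.55 in MC 2, 0.81 in MC 1 and 0.83 in MC 3, against 1.12 to 1.73 in LRWE. The list of adipocytes, cells rich in such transcripts, moved the same way, with a mean of 1.05 and a camera adjusted p of 0.0333 (adjusted p = 0.545 with an estimated correlation), a call lost without MC 2, MC 3, LRWE 1 or LRWE 3 (adjusted p 0.06 to 0.1). The mean of adipocytes was 1.86 without MC 1. Among the DSS libraries, the PPAR and proximal position scores were both lowest in MC 2 (-0.55 and 0.21) and highest in LRWE 2 (1.73 and 2.38). MC 1 was below LRWE 1 in the PPAR score (0.81 and 1.12) but above it in the proximal score (1.89 and 1.58). The segment of colon taken was not tested as a source of these differences. Without LRWE 2 the means of oxidative phosphorylation and ribosomal proteins were 0.44 and 0.39. The NRF2 list of oxidative stress genes had a mean of 0.58, with 10 of 20 higher adjusted over the list alone (camera adjusted p = 2.36e-06, adjusted p = 0.544 with an estimated correlation). Gclc, the catalytic subunit for glutathione synthesis, had 0.98 ± 0.30 (adjusted p = 0.164, and 0.031 without LRWE 1).

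Lists of the tissue below the epithelium were lower in LRWE. Fibrillar collagens and matrix had a mean of -1.53, with 17 of 20 members lower adjusted over the list alone (camera adjusted p = 1.21e-11, adjusted p = 0.544 with an estimated correlation). Means were -1.48 for neurons and glia, -1.21 for fibroblasts, -1.03 for endothelium and -0.81 for smooth muscle (camera adjusted p 1.66e-09 to 1.26e-05, adjusted p = 0.544 to 0.545 with an estimated correlation). Col3a1 had -1.29 ± 0.43 (adjusted p = 0.165), the vascular junction gene Cldn5 -0.95 ± 0.24 (adjusted p = 0.164) and Gfap -2.35 ± 0.47 (adjusted p = 0.164). Without LRWE 1 all 3 passed (adjusted p 0.0457, 0.0402 and 0.031). The fibroblast score was -0.94 in LRWE 1, -2.11 in LRWE 2 and -2.12 in LRWE 3, and the neuron and glia score was 1.14, -1.93 and 0.04. Without MC 2 the means of fibroblasts and endothelium were -0.76 and -0.68, and without LRWE 2 that of smooth muscle was -0.52. The skeletal muscle list was lower too, with a mean of -2.85 (-2.24 with groups at 0 set at the floor) and 6 of 15 members lower adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.171 with an estimated correlation, and 0.00805 by fry). The quality list of immediate early and dissociation stress genes, which respond to tissue handling, was also lower, with 14 of 17 members negative, a mean of -0.70 and a camera adjusted p of 0.0248 (adjusted p = 0.545 with an estimated correlation). Its scores were -0.43, -0.86 and -0.21 in LRWE and 0.14, 0.57 and -0.12 in MC, and the call was lost without MC 2 (adjusted p = 0.161) or LRWE 1 (0.0883), with a mean of -1.09 without LRWE 3. The list of distal colon position was lower as well, with a mean of -1.94, or -1.15 without MC 2 (camera adjusted p = 0.0179, adjusted p = 0.526 with an estimated correlation), and Hoxb13 had -5.12 ± 1.52 (adjusted p = 0.164, and 0.046 without LRWE 1). The proximal position list was higher, with a mean of 0.70 (camera adjusted p = 0.0118, adjusted p = 0.545 with an estimated correlation). It was called in 19 of 33 alternatives.

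Stat3 and Socs3 did not pass in this comparison, which covers RNA and not the activity of the proteins. Stat3 went from 177.7 to 125.2 CPM (-0.50 ± 0.31, adjusted p = 0.337) and Socs3 from 81.7 to 41.8 CPM (-0.97 ± 0.69, adjusted p = 0.409). Without MC 2 these values were -0.05 (adjusted p = 0.939) and 0.35 (adjusted p = 0.748). Other core values were -0.42 for Jak1, 0.25 for Jak2, -0.37 for Jak3, 0.21 for Tyk2, -0.31 for Stat2, -1.31 for Stat4, -0.41 for Stat5a, -0.36 for Stat5b and 0.16 for Stat6 (adjusted p 0.206 to 0.524). The core list had a mean of -0.28 (camera adjusted p = 0.486), with scores of 0.24 ± 0.23 in MC and -0.01 ± 0.09 in LRWE (mean ± SD, n = 3). The list of JAK/STAT targets and feedback had a mean of -0.31 (camera adjusted p = 0.548), with scores of 0.44 ± 0.43 in MC and 0.21 ± 0.12 in LRWE, and without MC 2 its mean was 0.04. The list of gp130 and IL-22 family signals and receptors, which lie upstream, was lower by camera, with a mean of -1.12 (-0.96 with groups at 0 set at the floor) and 14 of 19 members negative (camera adjusted p = 0.0429, adjusted p = 0.545 with an estimated correlation, and 0.132 by fry). No member passed, it was called in 13 of 32 alternatives, and the call was lost without MC 2 (mean -0.48, adjusted p = 0.0805), MC 3 (0.0645), LRWE 2 (0.0583) or LRWE 3 (0.186). The table's own KEGG term for JAK-STAT signalling, with 119 tested genes, had a mean of -0.614 (camera adjusted p = 0.091). Il6 had -0.72 ± 2.10 (adjusted p = 0.865, and 3.59 without MC 2), Il1b -0.77 ± 1.36 (adjusted p = 0.763) and Tnf -0.96 ± 0.68 (adjusted p = 0.406). All 13 tested inflammatory cytokines had negative values, with a mean of -1.69 (-1.45 with groups at 0 set at the floor) and a camera call (adjusted p = 0.0151, adjusted p = 0.545 with an estimated correlation), and the list call was lost without MC 2 (mean 0.17, adjusted p = 0.39), MC 3 (0.0538) or LRWE 3 (0.336). Chemokines (mean -1.49, or -1.37 with the floor), matrix remodelling proteases (-1.13), monocytes and macrophages (-0.64) and coagulation and complement (-1.53, or -1.39) were lower too (camera adjusted p 2.05e-05 to 0.0111). They were called in 28 to 32 of 33 alternatives, with no called member and an adjusted p of 0.545 to 0.657 with an estimated correlation. Neutrophils (0.0662), NF-kB targets (0.477) and interferon-stimulated genes (0.383, direction up) did not pass by camera.

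**Figure D4:**
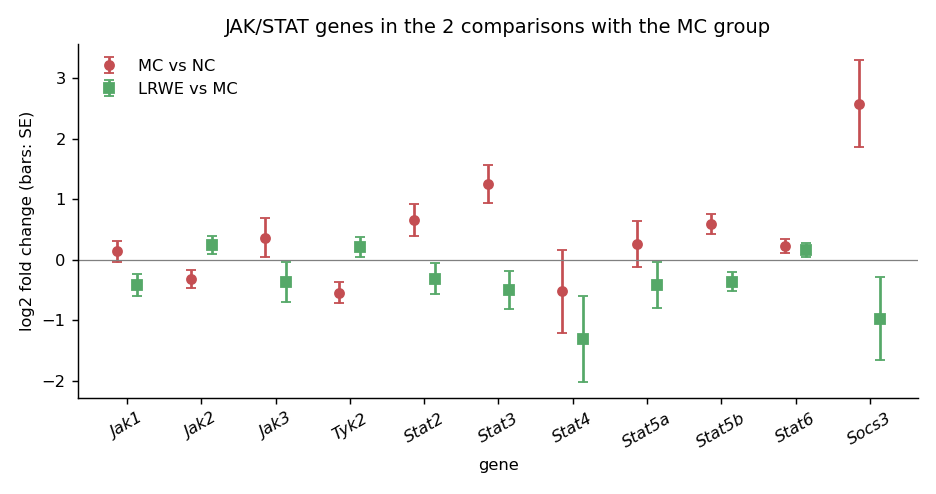
Log2 fold changes ± SE (edgeR, n = 3 per group) of core JAK/STAT genes and Socs3, for MC against NC (red circles) and LRWE against MC (green squares). Stat3 lies at 1.25 in MC against NC and at -0.50 in LRWE against MC, and Socs3 at 2.58 and -0.97, of which the latter was 0.35 without MC 2.

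Of the 1386 genes called in MC against NC, 69.6% had the opposite sign in LRWE against MC. Simulated LRWE mice drawn with the MC means gave 65.8% ± 0.894 (63.8 to 68.3 over 100 simulations), because both comparisons share the MC libraries. The covariance of the 2 sets of fold changes was -0.468, against -0.463 in the simulations. The simulated share is over 2480 called genes on average (2340 to 2640), and the slope was -0.0611 against -0.106 (-0.128 to -0.0865) in the simulations. The simulations drew genes independently with the same dispersion in all groups, so they hold no deviation common to a whole library. Their ranges therefore cannot decide whether changes were reversed. The share was 57.7% without MC 2 and 77.0% without LRWE 2. Reg3b (1.65 ± 0.62, adjusted p = 0.177) and Saa3 (0.66 ± 0.29, adjusted p = 0.213) had the same sign in LRWE against MC as in MC against NC.

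The comparison of LRWE with NC asks what remained different from control mice in treated mice, and antimicrobial genes were again higher. Reg3b rose by 9.85 ± 0.88 to 1562 CPM (adjusted p = 0.00206), Reg3g by 9.24 ± 0.96 (adjusted p = 0.00261) and Saa3 by 6.63 ± 0.38 (adjusted p = 0.000659). Reg3a was at least 107-fold higher (adjusted p = 0.00637), Ceacam12 at least 111-fold higher (adjusted p = 0.00565) and Ppp3r2, a testis calcineurin subunit, at least 191-fold higher (adjusted p = 0.0211). The antimicrobial list had 6 of 23 members higher and 1 lower (10 and 1 adjusted over the list alone), a mean of 1.9 (1.05 without LRWE 1 for epithelial antimicrobial defence) and a median of 0.37 (camera adjusted p = 1.76e-05, adjusted p = 0.359 with an estimated correlation). The 1 lower member, chosen after its values were seen, was lysozyme 1 (Lyz1, -3.29 ± 0.76, adjusted p = 0.0303). Muc2 rose by 2.22 ± 0.30 (adjusted p = 0.00523). Slc20a1 (-3.21 ± 0.40, adjusted p = 0.00456), Slc26a3 (-3.0 ± 0.43, adjusted p = 0.00617) and Best2 (-1.63 ± 0.26, adjusted p = 0.00880) stayed lower. Ocln had -0.92 ± 0.26 (adjusted p = 0.0559, and 0.0321 without MC 2). The call of Ppp3r2 was lost without NC 1, NC 2, NC 3 or LRWE 3, and that of Lyz1 without NC 2, NC 3, LRWE 1, LRWE 2 or LRWE 3 (adjusted p 0.0526 to 0.0975), and the other calls of this group held without each library.

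Genes of fatty acid and redox metabolism were higher than in control mice. Fabp2, a fatty acid binding protein of the small intestine, rose by 4.72 ± 0.90 (adjusted p = 0.0157), Acaa1b by 5.39 ± 0.92 (adjusted p = 0.0111) and Pparg by 2.86 ± 0.48 (adjusted p = 0.0103). The PPAR list had 7 of 26 members higher (14 adjusted over the list alone), a mean of 1.4 and a camera adjusted p of 4.19e-08 (adjusted p = 0.447 with an estimated correlation). The proximal position list rose in the same comparison, and the segment of colon taken was not tested as a source of these rises. The list of adipocytes had a mean of 0.55 and a camera adjusted p of 0.0244 (adjusted p = 0.556 with an estimated correlation), lost without NC 2 (mean 0.23, adjusted p = 0.118) or LRWE 3 (0.0546), and without NC 3 the mean was 1.66. Its scores ran from -1.14 to 1.24 in NC and from 0.40 to 1.26 in LRWE. Its 2 called members, chosen after their values were seen, were Lpl (1.98 ± 0.33, adjusted p = 0.0103) and Cidec (3.04 ± 0.78, adjusted p = 0.0414), the latter also in the PPAR list. The call of Lpl was lost without NC 1 or NC 2, and that of Cidec without any 1 library but NC 3 or MC 2 (adjusted p 0.0534 to 0.148). Gclc rose by 1.65 ± 0.30 (adjusted p = 0.0142), Nqo1 by 2.48 ± 0.63 (adjusted p = 0.0402) and the malic enzyme Me1, chosen after its values were seen, by 1.64 ± 0.16 (adjusted p = 0.00236). The NRF2 list had 10 of 20 members higher and 1 lower (12 and 1 adjusted over the list alone), a mean of 0.71 and a camera adjusted p of 2.19e-06 (adjusted p = 0.359 with an estimated correlation, and 0.0474 by fry). The 1 lower member, chosen after its values were seen, was Prdx6, from 4617 to 1026 CPM (-2.17 ± 0.47, adjusted p = 0.0250). Me1 was called without each library. The calls of Fabp2, Acaa1b, Gclc, Nqo1 and Prdx6 were lost without NC 1, those of all of these and Pparg without NC 2 or NC 3, those of Nqo1 and Prdx6 without LRWE 3, that of Nqo1 without MC 3 or LRWE 2, and that of Prdx6 without LRWE 1 (adjusted p 0.0518 to 0.14).

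Immunoglobulin, stromal and distal genes were lower. Jchain had -3.73 ± 0.60 (adjusted p = 0.00862), and the B and plasma cell list had 9 of 25 members lower and 1 higher (22 and 1 adjusted over the list alone), a mean of -5.95 (-5.34 with groups at 0 set at the floor) and a camera adjusted p of 2.35e-08 (adjusted p = 0.447 with an estimated correlation). The 1 higher member was Sdc1 (1.66 ± 0.18, adjusted p = 0.00346), which epithelial cells also express. The endothelial and stromal gene Cd34 fell by 2.08 on the log2 scale (SE 0.31, adjusted p = 0.00676) and Cldn5 by 1.9 (SE 0.25, adjusted p = 0.00481). The fibroblast list had 4 of 20 members lower (9 adjusted over the list alone), with Pi16, chosen after its values were seen, at -5.86 ± 0.76 (adjusted p = 0.00481). The list mean was -1.38 (camera adjusted p = 2.19e-06, adjusted p = 0.447 with an estimated correlation). Itih2 was at least 946-fold lower (adjusted p = 0.0110) and Casp14, a caspase of squamous epithelium, at least 1200-fold lower (adjusted p = 0.0417). The calls of Jchain, Sdc1, Cd34, Cldn5 and Pi16 held without each library. That of Itih2 was lost without NC 2, and that of Casp14 without NC 1, NC 2, NC 3, LRWE 1, LRWE 2 or LRWE 3 (adjusted p 0.0503 to 0.106).

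Position genes also differed between LRWE and NC. Slc37a2 had -8.94 ± 0.89 (adjusted p = 0.00236) and Sfrp2 -2.90 ± 0.38 (adjusted p = 0.00485), and Hoxb6 rose by 4.84 ± 0.70 (adjusted p = 0.00637). In no position list, the mucosal pentraxin Mptx1 (-10.91 ± 1.26, adjusted p = 0.00404) and the sodium pump regulator Fxyd4 (-11.68 ± 1.82, adjusted p = 0.00804) were among the largest falls. These 5 calls held without each library. Hoxb13 (-8.76 ± 1.76) and Hoxd13 (-8.96 ± 1.80), chosen after their values were seen, passed in this comparison (adjusted p = 0.0189 for both). The distal list had 5 of 11 members lower and 1 higher (5 and 2 adjusted over the list alone), a mean of -2.79 (-3.07 with groups at 0 set at the floor) and a camera adjusted p of 0.000257 (adjusted p = 0.157 with an estimated correlation, and 0.00291 by fry). Besides Slc37a2, Sfrp2, Hoxb13 and Hoxd13 the lower member was Hoxd12 (-7.65 ± 1.63, adjusted p = 0.0233), chosen after its values were seen, and the higher one was the carbonic anhydrase Car1 (3.91 ± 0.82, adjusted p = 0.0221). The proximal list had 7 of 12 members higher (7 higher and 1 lower adjusted over the list alone), a mean of 2.13 and a camera adjusted p of 3.62e-07 (adjusted p = 0.359 with an estimated correlation, and 0.0329 by fry). The calls of Hoxb13, Hoxd13, Hoxd12 and Car1 were lost without NC 1, NC 2, NC 3 or LRWE 3, and that of Hoxd12 without LRWE 2 (adjusted p 0.0537 to 0.0989).

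Among JAK/STAT genes in LRWE against NC, Bcl2l1 (1.69 ± 0.13, adjusted p = 0.00129) and Pim1 (1.1 ± 0.25, adjusted p = 0.0299) were the 2 called members of 22 in the target list (3 higher and 1 lower adjusted over the list alone). The list mean was 0.24 (camera adjusted p = 0.0668). Stat3 had 0.74 ± 0.31 (adjusted p = 0.16) and Socs3 1.61 ± 0.70 (adjusted p = 0.178), and both passed without MC 2 (adjusted p 0.0323 and 0.0386). The core list had a mean of -0.04 and a camera direction of up (adjusted p = 0.563). Il6 was at least 26.1-fold higher (adjusted p = 0.181), Tnf had 1.28 (adjusted p = 0.274) and Il1b 2.42 (adjusted p = 0.326). The call of Pim1 was lost without NC 1, NC 2, NC 3, LRWE 2 or LRWE 3 (adjusted p 0.0665 to 0.119), and that of Bcl2l1 held without each library.

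In LRWE against NC, 1314 genes were higher and 865 lower (2179, or 10% of those tested), and 1410 of them differed by at least 2-fold. The groups did not overlap for 8076 genes (37.1%, where chance gives 10% on average over splits, from which a single split can lie far). The count of calls was 534 without NC 1, 459 without NC 2, 558 without NC 3, 1410 without LRWE 2 and 1026 without LRWE 3. Of the 48 lists, 15 rose and 14 fell, and none held with an estimated correlation. The calls against NC overlapped by 404 genes higher and 403 lower in both MC and LRWE, and 0 genes were called in opposite directions. Independent lists of these sizes would share 37.3 and 30.5 genes. Unchanged groups against the same controls shared 0.02 and 0 in 100 simulations. A count near 0 is fixed by drawing every group unchanged, so it does not test the overlap of lists of these sizes. The covariance of the fold changes was 0.94 against 0.261 in the simulations, and part of the overlap may come from the shared control libraries, which are too few to split.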

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

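The planned fit of FPKM with a pseudocount of 1 and a filter at FPKM 1 became an alternative when counts became the main input. The scalings of counts other than TMM, robust edgeR, voom with quality weights, DESeq2 and both fits without 2 libraries were chosen after seeing the data. FPKM alternatives change the test and the scaling together, and arrayWeights did not converge. Of the called genes followed here, 75 in MC against NC and 93 in LRWE against NC, none changed sign. In LRWE against MC the mean of inflammatory cytokines changed sign from -1.69 to 0.17 without MC 2, and that of B and plasma cells from -3.63 (-3.02 with groups at 0 set at the floor) to 0.11 with arrayWeights. In 10560 of the checks of single named genes the direction and the call stayed the same. The call was lost in 744 and gained in 624, and in 170 a value called in neither fit changed sign. Depth was 59042063 to 65042857 counts per library. With 3 mice per group and 200 changed genes, simulated changes of 1 on the log2 scale were recovered in 4.21% of cases for MC against NC. Except where a reason is given, the cause of a difference between settings was not tested.

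The 1386 calls of MC against NC became 3781 with the 2 groups alone, 2271 with FPKM and a pseudocount of 1, 2091 with 0.5, 2526 with median-of-ratios FPKM, 3489 with quantile normalisation and 2571 with FPKM scaled to genes under 1%. They became 2240 without the trend, 2254 with robust hyperparameters, 5122 with arrayWeights, 5205 with voom weights, 3762 with DESeq2 (1380 of the 1386 among them) and 2797 at an unadjusted p with a 2-fold change. Without MC 2 and LRWE 2 they were 3301, and without LRWE 2 and LRWE 3 they were 3484. The 0 calls of LRWE against MC became 4842 with arrayWeights, 2901 with voom weights, 2001 with DESeq2 and 2147 at an unadjusted p with a 2-fold change. The 2179 calls of LRWE against NC became 6688, 6142 and 4398 with arrayWeights, voom weights and DESeq2, 721 without LRWE 2 and LRWE 3, which leaves 1 LRWE mouse and takes the spread from the other groups, and 1410 when a 2-fold change was also required, which can only remove calls. With every gene kept, the counts were 1023, 0 and 1497 over 34101 genes.

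Leaving out 1 library at a time gave 281 to 3318 genes for MC against NC, 0 to 2436 for LRWE against MC and 459 to 2725 for LRWE against NC. Lists called ranged from 17 to 21, 21 to 29 and 26 to 30 in the same order. The core list mean ranged from 0.07 to 0.31 for MC against NC and from -0.36 to -0.11 for LRWE against MC. The target list mean ranged from 0.20 to 0.66 and from -0.43 to 0.04, with 0.04 without MC 2. The share of MC changes with the opposite sign in LRWE against MC ranged from 57.7% to 77.0%.

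The replicate numbers do not pair the mice, since deviations of libraries with the same number correlated at -0.162 to 0.0313 and those with other numbers at -0.115 to 0.238. A replicate block gave 306 calls for MC against NC and 600 for LRWE against NC, and it uses up residual degrees of freedom.

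Of the lists called in MC against NC (19), 6 passed with a filter at FPKM 5, 9 with FPKM under each pseudocount (1, 0.1, 0.5), under a common sum, median-of-ratios or the sum of genes under 1%, without the trend, with robust hyperparameters and with arrayWeights, 11 with quantile normalisation, 10 with voom weights, 4 by fry and 0 with an estimated correlation. In LRWE against MC (28), 18 passed with FPKM and a pseudocount of 1 or 0.5, quantile normalisation, no trend, robust hyperparameters and arrayWeights, 17 with FPKM scaled to genes under 1%, 2 by fry and 0 with an estimated correlation. In LRWE against NC (29), 19 passed with quantile normalisation, 8 by fry and 0 with an estimated correlation.

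The JAK/STAT target list in MC against NC (mean 0.55, adjusted p = 0.0173) no longer passed with a filter at FPKM 5 (0.70), the 2 groups alone (0.55), FPKM with a pseudocount of 1 (0.49), 0.1 (0.57) or 0.5 (0.53), a common sum (0.66), median-of-ratios FPKM (0.40), quantile normalisation (0.43), FPKM scaled to genes under 1% (0.55), no trend (0.49), robust hyperparameters (0.49), arrayWeights (0.28), voom weights (0.30), without MC 2 and LRWE 2 (0.20), without LRWE 2 and LRWE 3 (0.54), with an estimated correlation (0.55, adjusted p = 0.618) or by fry (0.55, adjusted p = 0.168). The opposite-sign share (69.6%) was 62.3% with a filter at FPKM 5, 78.7% with the 2 groups alone, 62.5% with a pseudocount of 0.1, 58.5% with a common FPKM sum and 62.3% with library totals.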

Other observations

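Of the tests of 3 patterns, all but the place of LRWE 1 between the groups were chosen only after the result was seen, and so were the gene groups described first.

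Absorptive colonocyte genes were higher in LRWE than in NC, with 12 of 25 members called higher and 2 lower (14 and 5 adjusted over the list alone), a mean of 1.27 and a camera adjusted p of 5.41e-05 (adjusted p = 0.359 with an estimated correlation). Dhrs9 (4.04 ± 0.56, adjusted p = 0.00558) and Emp1 (4.17 ± 0.51, adjusted p = 0.00443) rose, while Slc26a3 (-3.0 ± 0.43, adjusted p = 0.00617) and Slc37a2 (-8.94 ± 0.89, adjusted p = 0.00236) of the same list fell. Dhrs9 was chosen after its values were seen, and these 4 calls held without each library. The glycolysis and hypoxia list had 6 of 25 members higher in LRWE than in NC (10 adjusted over the list alone), with Ndrg1 at 2.85 ± 0.38 (adjusted p = 0.00495), a mean of 0.65 and a camera adjusted p of 1.76e-05 (adjusted p = 0.502 with an estimated correlation). The enteroendocrine peptides Sst and Nts rose in MC against NC, somatostatin (Sst) from 41.8 to 427.6 CPM (3.35 ± 0.50, adjusted p = 0.00859) and neurotensin (Nts) from 0.327 to 30.5 CPM (6.55 ± 1.34, adjusted p = 0.0252). The list of enteroendocrine and tuft cells did not pass, with 4 of 23 members called (6 adjusted over the list alone), a mean of 0.83, a median of 0.251 and a camera adjusted p of 0.0566. The call of Sst was lost without NC 1 or NC 2, and that of Nts without NC 1, NC 2, NC 3, MC 1 or MC 3 (adjusted p 0.0540 to 0.103). In the deposited annotation, the term extracellular matrix had 184 tested genes with a mean of -1.11 in LRWE against MC (camera adjusted p = 4.45e-13). No correlation was estimated for terms, and the list of collagens and matrix had an adjusted p of 0.544 with one.

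The distal genes Hoxb13 and Hoxd13 lay below every NC library and the proximal gene Hoxb6 above every NC library in 6 of 6 DSS libraries. Less epithelium in the DSS libraries is argued against, since it needs epithelial genes to fall as far as the distal Hox genes, and at most 9.52% of 84 members of the goblet, absorptive, crypt and enteroendocrine lists did so in any DSS library. Hoxb13 and Hoxd13 fell least in MC 2 (-2.28 and -2.11), where the median of these members was -0.27 (quartiles -0.87 and 0.73). The crypt list did fall against NC, with a mean of -1.13 in MC and -1.08 in LRWE, and the absorptive list, with a score of 0.00 in MC 2, did not pass in MC (camera adjusted p = 0.201). A shift that grows with the inflammatory transcripts of a library could also give it and stays open, since 3 libraries per group are too few to test a relation. In 2 of 2 DSS groups the library with the highest cytokine score (MC 2 and LRWE 1) also had the highest distal score, the opposite of what such a shift would give. Tissue taken nearer the proximal end in the DSS groups could give the pattern and stays open, since 5 of the 10 position genes outside the Hox family (Sfrp2, Slc37a2 and Osr2 among them) went the way of their list in LRWE against NC and the others, such as Car1 and Gsdmc3, did not. Among the DSS libraries, however, Car1 ran with the proximal genes Osr2 and Hoxb6. All 3 were lowest in MC 2 (801, 2.12 and 11.6 CPM) and highest in LRWE 2 (16200, 244 and 151) and LRWE 3 (9500, 205 and 156). The distal place given to Car1 was not tested, and the count of 5 of 10 depends on such places. An effect of DSS injury or repair on position genes is the biological alternative and cannot be told apart from the sampled position, because the segment is not given in the sources used here.

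In LRWE 2 and LRWE 3, 5 of 5 stromal lists (fibroblasts, endothelium, smooth muscle, neurons and glia, collagens) lay below every MC library. Lower library totals are argued against, as the smaller total of these libraries was 64.2 M counts, above every MC library. LRWE 2 and LRWE 3 nevertheless had the fewest genes with a count (21218 and 23238, against 24434 to 26019 elsewhere). LRWE 2 also had the lowest TMM factor (0.8436) and quality weight (0.247), while LRWE 3 had the highest quality weight (2.87). Whether fewer detected genes are a cause or a result of the pattern was not tested. Less of the colon wall below the epithelium in these tissue pieces may give the pattern, and it stays open because 1 of 4 epithelial lists lay above every MC library in both. An effect of the extract stays open too, with 3 of 5 stromal lists below every MC library in LRWE 1. These were neurons and glia (1.14, lowest MC library 1.49), collagens (-0.40, lowest -0.15) and fibroblasts, which tie with MC 1 at the digits given (-0.94).

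LRWE against MC gave 0 calls with all libraries and 2436 without LRWE 1. On an axis of 500 genes built without LRWE 1, with 0 at the MC mean and 1 at the mean of LRWE 2 and LRWE 3, LRWE 1 lay at 0.201. Each other library was placed on its own axis, with genes and group means taken from the libraries left in. These places were 0.581 (MC 1), 0.00431 (MC 2), 0.477 (MC 3), 1.22 (LRWE 2) and 0.634 (LRWE 3). A wrong label on an MC library, called LRWE 1, may give the 0 calls, and the test cannot decide it. The MC libraries themselves lay from 0.00431 to 0.581, and places on different axes are not directly comparable. Some values go with the label of LRWE 1, found afterwards, as its skeletal muscle score was -2.05 (MC -0.80 to 0.08, LRWE 2 and LRWE 3 -2.59 and -2.15), its score for goblet cells was 0.49 (MC -0.20 to 0.05), and Actc1 was at 0 CPM in all 3 LRWE libraries. These were picked from differences of LRWE against MC that included LRWE 1, so their agreement is partly built in. Other values go against the label. LRWE 1 correlated at r = 0.9546 with MC 1 and 0.9545 with MC 3, against 0.9394 with LRWE 3 and 0.8943 with LRWE 2, though at 0.9281 with MC 2. Of the 500 genes on its axis, 9.6% lay nearer the LRWE mean. Spread between the LRWE mice could also account for the 0 calls, with a median SD 1.88 times that of NC, but this ratio cannot settle it. The MC ratio was 1.5, and MC against NC gave 1386 calls. LRWE against NC used the same LRWE libraries and gave 2179 calls. The spread of each gene was estimated over all groups together. The near-equal median standard errors (0.414 against 0.413) are therefore built in and do not measure the LRWE spread. The calls of MC against NC carry the LRWE spread too, and were 3781 with the 2 groups alone, so they are no independent comparison. The distance of LRWE 1 from LRWE 2 and LRWE 3 is also part of the LRWE spread. A weak response to the extract in 1 mouse was not tested. The 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split gave 1386 genes for MC against NC and the highest other 0, so 1 of 10 was as large. For LRWE against MC the real split gave 0 and the highest other 3, so 10 of 10 were as large, but a real count of 0 fixes that outcome and it tests nothing. For LRWE against NC it gave 2179 and the highest other 0, so 1 of 10 was as large.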
